A study of Homo sapiens with 18 samples.

How the data were processed

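The libraries were made from total RNA of Cas9-expressing KNS-42 cells on day 7 after lentiviral transduction of a guide RNA, with a kit that sequences the 3' ends of polyadenylated transcripts, per the labels' protocols. Reads therefore lie near the 3' end of each transcript, so a count does not grow with transcript length and reads need not cover a guide's target site. Guide sequences were not given in the sources used here.

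The deposited table holds a normalised signal for 58050 Ensembl gene identifiers in 18 libraries, which the authors made by dividing gene counts by 1 size factor per library, as the values show. The submitters' processing notes name STAR 2.5.2b, RSEM 1.3.0, featureCounts 1.5.1, limma and the build GRCh38, without saying which tool made these values, and the annotation version and strand setting were not given in the sources used here. Dividing each column by its smallest positive value gave whole reads for 100% of values in all 18 libraries, within a tolerance of 0.01. The deposited size factors lay between 0.987 and 1.02 times those of the median-of-ratios method. Recovered totals ranged from 5.67 M to 13.2 M reads (M, 1e6). Limits from a count of 0 (3 reads) and intervals cover counting error only, since the reads carry no molecular identifiers that were used here.

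Groups came from the sample labels, which name the cells, the guide and a replicate number. Gene symbols and positions came from GENCODE 29 on GRCh38, which held 57446 of the identifiers, and 56947 had a symbol. The 18 columns of the table matched 1 sample each by name. No replicate pair agreed within sampling noise: chi-square per degree of freedom over genes was between 22.6 and 160.6 for pairs within a group. The first 3 principal components held 26.5, 14.1 and 12.5% of the variance.

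Values were tested as log2(normalised value + 1) with limma 3.58.1 in R 4.3.3, in a model of 6 group means over all 18 libraries with 12 residual degrees of freedom, moderated with an intensity trend. Fold changes are on this scale, which understates the change of genes with few reads. Genes with a value of at least 10 in at least 3 libraries were kept, 15228 in all, and 29485 were at 0 in every library. The 9 comparisons were guide 395 against AAVS1 in each kind of cell, the 3 differences between these effects, and the 3 differences between cells under the control guide. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. This test, the gene lists and the rule for naming genes were chosen before the data were examined.

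Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, with an estimated correlation and fry beside it. Of 35 lists with 923 genes, 2 of which were not found, 809 genes were tested, and the 31 lists with at least 5 tested members were used. The written plan counted 1 list too many, and its own text holds 35. With the estimated correlation no list passed in any of the 9 comparisons, and fry passed the proteasome list in parental cells alone. The lists overlap in part, and ribosomal protein and mitochondrial genes have pseudogene copies that can share reads.

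Named genes were DDX3X and DDX3Y in every comparison. In addition, among called genes above the 40th percentile of mean expression, with a proper symbol and no overlap between the compared groups, the 10 with the largest positive and the 10 with the largest negative log2 fold change were named. Each list past its test or with 3 called members gave up to 4 members with the smallest p, and called members of X-Y gene pairs would have been named, of which there were none.

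The replicate numbers were checked for pairing through the correlation of same-numbered libraries' deviations from their group means. In parental cells these were 0.57, 0.201 and 0.28, all above 0.1, so the numbers were taken to pair the parental libraries. Values with the replicate number as a block stand beside parental results where they changed a call or moved a count by over 1.5 times. That block is 1 effect per number shared by all 18 libraries, so it assumes the numbers mean the same in every cell line. For DDX3X in parental cells the limma adjusted p was 0.0578 with it and 0.0914 with a block within each cell line. The labels do not say what a number stands for.

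Alternatives were other pseudocounts (0.1 and 5), no filter or a filter of 50, median-centring, quantile normalisation, no intensity trend, robust moderation, a fit on the compared groups alone, the replicate block, a fold change minimum, leaving out each library, and count models on the recovered reads, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0. The following were added after the data were seen: a block within each cell line, library quality weights, leaving out both replicate 1 libraries labelled DDX3Xoe, leaving out each library for the gene lists, and leaving out both libraries of a replicate number for the lists in DDX3Xoe and DDX3Yoe cells.

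The steps were tested on simulated counts of 14884 genes drawn from a negative binomial with each gene's mean and dispersion in the real libraries, with known fold changes. For guide 395 in parental cells limma recovered 0% of genes changed 1.5-fold, 6.52% at 2-fold, 52.1% at 4-fold and 85.4% at 8-fold, with 1 false call. DESeq2 recovered 68.8% at 4-fold with 9 false calls and edgeR 56.2% with 1. Changes of 2-fold or less in single genes were therefore mostly not detectable in these libraries.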

Results

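Gene expression was measured in KNS-42 cells, a cell line made to express the Cas9 nuclease. Parental cells were compared with cells that also expressed a codon-optimised DDX3X (DDX3Xoe) or a codon-optimised DDX3Y (DDX3Yoe). Each kind of cell received guide RNA 395, which targets the endogenous DDX3X gene, or a control guide against AAVS1, a safe-harbour site inside the PPP1R12C gene, and RNA was taken on day 7 after transduction. The 6 groups had 3 replicate libraries each, and the 18 libraries held between 5.67 M and 13.2 M reads on genes (M, 1e6), with a median of 8.85 M. The library with the fewest reads, DDX3Xoe with guide 395 replicate 2, also had the fewest genes with a read, 15744. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these samples, which may be partly technical.

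DDX3X (ENSG00000215301) encodes a DEAD-box RNA helicase and lies on the short arm of chromosome X, at 41333284 to 41364472 on the plus strand of GRCh38. In parental cells its normalised read count was 1811 ± 100 (SD, n = 3) with the control guide and 886 ± 58.8 (SD, n = 3) with guide 395, and no library of one group overlapped the other. The log2 fold change was -1.03 with a standard error of 0.30 and a limma adjusted p of 0.08, so it missed the threshold of 0.05. It passed with DESeq2 (adjusted p 0.0265) and, in limma, when both replicate 1 libraries labelled DDX3Xoe were left out of the fit (adjusted p 0.0123). In DDX3Yoe cells the counts were 1458 ± 90.5 (SD, n = 3) with the control guide and 757 ± 114 (SD, n = 3) with guide 395, again without overlap, with a log2 fold change of -0.95 and a limma adjusted p of 1. In DDX3Xoe cells the 3 libraries labelled AAVS1 held 668, 1504 and 1162 normalised reads and the 3 labelled 395 held 1416, 716 and 578, for replicates 1, 2 and 3. The replicate 1 libraries thus ran against their guide labels, and the log2 fold change over all 6 was -0.33 with a limma adjusted p of 1. It was -1.04 without both of them (adjusted p 1). With 1 library left out it was -0.66, -0.074 and -0.26 without the library labelled AAVS1 replicate 1, 2 and 3, and -0.71, -0.22 and -0.064 without the library labelled 395 replicate 1, 2 and 3. These 2 libraries are called by their labels throughout. Reads from 3' tags need not cover the site that the guide targets, and a codon-optimised transgene need not give reads assigned to the endogenous gene, so these counts check the labels only in part. DDX3Y had 0 reads in all 18 libraries, those labelled DDX3Yoe included, as did the other Y-linked members of X-Y gene pairs that were counted. A count of 0 allows up to 3 reads per library, which is 0.529 CPM in the library with the fewest reads.

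**Figure D1:**
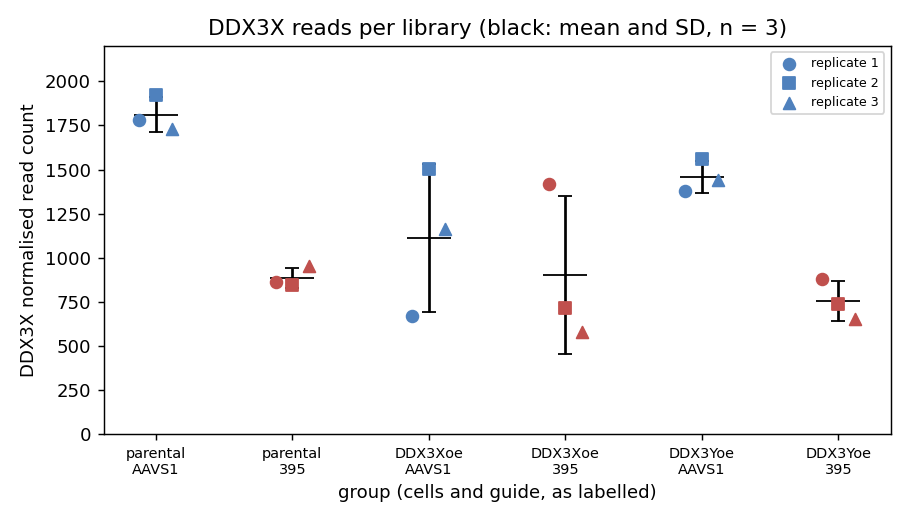
Normalised DDX3X read count (vertical axis) in each of the 18 libraries, by cells and guide (horizontal axis). Symbols give the replicate, blue the AAVS1 guide and red guide 395, and black lines the mean and SD of 3 libraries. In parental and DDX3Yoe cells the groups do not overlap, while the replicate 1 libraries labelled DDX3Xoe stand at 668 with AAVS1 and 1416 with guide 395.

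Guide 395 in parental cells asks what targeting the endogenous gene does when no DDX3 transgene is present. Interferon-stimulated genes were higher as a list, and single genes such as the actin gene ACTA2 and the collagen gene COL1A1 fell. The lists of ribosomal protein and of G2/M genes were lower, without a member past the threshold over all genes, and all 3 list calls were lost with an estimated correlation (adjusted p = 0.38, 0.38 and 0.562 with an estimated correlation). Of 15228 genes tested, 149 were higher and 122 lower with guide 395 (limma with an intensity trend, Benjamini-Hochberg adjusted p under 0.05), and 254 of these 271 changed by at least 1 on the log2 scale. The transcript HCP5, from the class I region of the major histocompatibility complex on chromosome 6 (31400702 to 31477506), rose from 77.2 ± 20.7 to 1123 ± 104 normalised reads (SD, n = 3), a log2 fold change of 3.87 (limma adjusted p 0.00301). ACTA2, smooth-muscle actin, on chromosome 10 (88935074 to 88991339), fell from 1107 ± 254 to 203.6 ± 34.3 (SD, n = 3), a log2 fold change of -2.43 (limma adjusted p 0.000633).

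The list of interferon-stimulated genes was higher with guide 395 in parental cells, with a median log2 fold change of 1.68 and 41 of its 42 measured members above 0 (camera adjusted p 2.27e-19). Over all genes tested 7 members passed, and 30 passed when adjusted over the list alone. The call was lost with an estimated correlation between genes (adjusted p = 0.38 with an estimated correlation), and fry gave an adjusted p of 0.08. ISG20, an exonuclease induced by interferon, had a log2 fold change of 4.23 (SE 0.82, limma adjusted p 0.0154). IFIT2, which binds viral RNA, rose by 3.22 (adjusted p 0.0174), and IFI27 by 3.30 (adjusted p 0.0369). HLA-B, an antigen-presenting molecule, rose by 2.89 (adjusted p 0.0139), and the peptide transporter gene TAP1 by 2.07 (adjusted p 0.0143). HLA-B can share reads with related genes, so its own value is uncertain. Outside the list, APOL1, a lipoprotein component, rose by 3.39, SERPING1, the complement C1 inhibitor, by 2.76, THEMIS2 by 3.02 and GMPR, a purine reductase, by 2.67. ZDHHC8BP, a pseudogene that may share reads with its parent gene ZDHHC8, rose by 3.50 (adjusted p 0.000633).

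**Figure D2:**
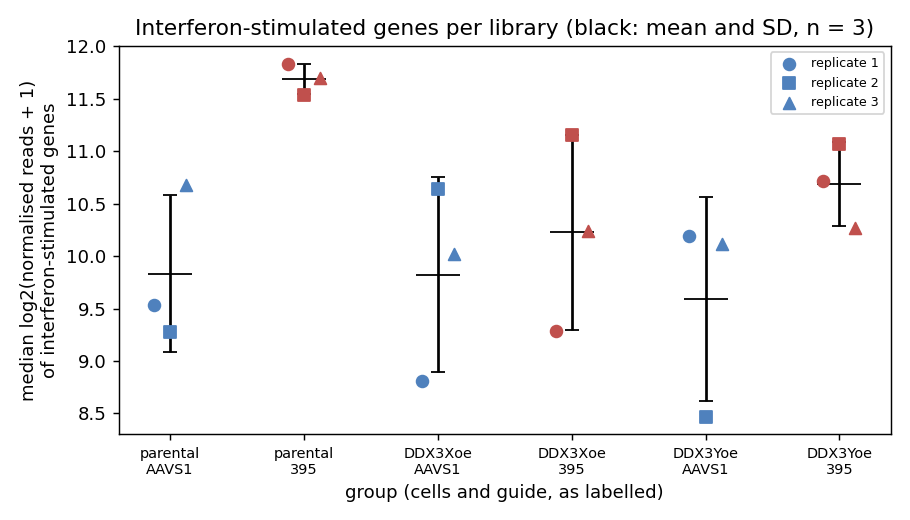
Median log2(normalised reads + 1) over the 42 interferon-stimulated genes (vertical axis, which does not start at 0) in each of the 18 libraries, by cells and guide (horizontal axis). Symbols give the replicate, blue the AAVS1 guide and red guide 395, and black lines the mean and SD of 3 libraries. In parental cells the libraries with guide 395 lie between 11.5 and 11.8 and those with AAVS1 between 9.28 and 10.7.

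The list of NF-kB and inflammatory genes was also higher, with a median of 1.08 and 15 of 18 members above 0 (camera adjusted p 8.56e-05). It too was lost with an estimated correlation (adjusted p = 0.38 with an estimated correlation). PTGS2, the inducible cyclooxygenase, was the member past the threshold over all genes (log2 fold change 1.83, adjusted p 0.0113), and 6 members passed when adjusted over the list alone. The chemokine gene CCL5 had a log2 fold change of 3.66 with an adjusted p of 0.0654, and passed with the replicate number as a block (0.0282), as did NFKB1 at 1.29 (0.078, blocked 0.0496). The list of proliferation and apoptosis regulators was higher by a median of 0.35 (camera adjusted p 0.0492, adjusted p = 0.38 with an estimated correlation), and none of its 23 members passed in limma over all genes or over the list alone. Among them, the inhibitor of apoptosis gene BIRC3 had an adjusted p of 0.119 over all genes and passed with the block (0.0168).

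Cytosolic ribosomal protein genes fell as a list, with a median log2 fold change of -0.72 and 72 of 78 members below 0 (camera adjusted p 2.35e-13), and this call was lost with an estimated correlation (adjusted p = 0.38 with an estimated correlation). No single member passed in limma, over all genes or over the list alone: RPLP0 went from 8134 ± 2506 to 3359 ± 473 normalised reads (SD, n = 3, limma adjusted p 0.0871), while RPL9 at -1.45 (0.0777) and RPL15 at -0.83 (0.0787) passed with the block (0.0376 and 0.0442). The G2/M and mitosis list was lower by a median of -0.89, with 41 of 43 members below 0 (camera adjusted p 2.67e-07, adjusted p = 0.562 with an estimated correlation). TOP2A, the topoisomerase of dividing cells, went from 6877 ± 2570 to 1752 ± 669 normalised reads (SD, n = 3, limma adjusted p 0.0952) and the mitotic kinase gene PLK1 had a log2 fold change of -1.65 (0.0896), and both passed with the block (0.034 each). The proteasome list fell by a median of -0.40, with 29 of 31 members below 0 (camera adjusted p 3.42e-05, adjusted p = 0.201 with an estimated correlation), and was the list that passed with fry (adjusted p 0.0123). Of its members, 3 passed when adjusted over the list alone, and PSMD7 at -0.80 and PSMD1 at -0.68 passed over all genes with the block (0.0426 and 0.038). Nuclear-encoded oxidative phosphorylation genes fell by a median of -0.37 (camera adjusted p 5.13e-06, adjusted p = 0.434 with an estimated correlation), with COX4I1 past the threshold at -1.04 (adjusted p 0.0484) and COX7C past it with the block (-1.09, 0.0262). Mitochondrially encoded transcripts fell by a median of -0.52 (camera adjusted p 0.00379, adjusted p = 0.562 with an estimated correlation), and their share of reads was 7.78 to 11.1% with guide 395 and 11.3 to 16.5% with the control guide.

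Extracellular matrix and mesenchymal genes had 4 members lower and none higher over all genes, and 7 lower when adjusted over the list alone. Besides ACTA2 these were COL1A1, the main fibrillar collagen chain, from 287.6 ± 64.1 to 52 ± 6.45 normalised reads (SD, n = 3, limma adjusted p 0.000924), TAGLN, an actin-binding protein, at -1.62 (adjusted p 0.0232) and COL5A2 at -1.08 (adjusted p 0.0445). The list as a whole had a median of -0.14 (camera adjusted p 0.0214, adjusted p = 0.434 with an estimated correlation). Outside the list, the actin gene ACTG2 fell by 2.77 and TMOD1, which caps actin filaments, by 2.22. ACO1, the cytosolic aconitase that also regulates iron, fell by 2.99 (adjusted p 0.00314), and the long non-coding RNA MIAT by 2.22 (adjusted p 0.00932). SUSD4 fell by 2.15, PLPPR4 by 2.13 and KCNN3 by 2.11, and the Wnt antagonist gene SFRP2 fell from 491.9 ± 278 to 104.2 ± 21 normalised reads (SD, n = 3). Other lists that were lower were cholesterol synthesis at a median of -0.44 (camera adjusted p 0.00436, adjusted p = 0.562 with an estimated correlation), where ACAT2 at -1.19 passed with the block (0.0164), DNA replication and S phase at -0.41 (0.0104, adjusted p = 0.847 with an estimated correlation, with same-numbered pairs at -0.84, -0.70 and 0.24) and translation factors at -0.22 (0.0104, adjusted p = 0.38 with an estimated correlation). MYC targets stood at -0.20, with same-numbered pairs at -0.15, 0.0095 and 0.23 (camera adjusted p 0.0492, adjusted p = 0.434 with an estimated correlation, and 0.0686 with the replicate number as a block), and were lost too with median-centring (0.0573) and without both replicate 1 libraries labelled DDX3Xoe (0.0554), which also ended the call of the apoptosis regulators (0.0523).

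The count of 271 genes in parental cells depended on the design and on single libraries. With the replicate number as a block it was 677, 336 higher and 341 lower, all 271 among them, and DESeq2 called 927. It was 139 without AAVS1 replicate 1, 60 without AAVS1 replicate 2, 68 without guide 395 replicate 1, 91 without guide 395 replicate 2 and 62 without guide 395 replicate 3, while the fit on the 6 parental libraries alone gave 83 and the fit without a filter on low values 159. Of the 27 genes of this comparison named by the rule set beforehand and past the threshold, those that passed whichever of the 6 libraries was left out included ACTA2, COL1A1, HCP5, ZDHHC8BP, ACO1, ACTG2 and TMOD1. Of the 27, 11 were lost without AAVS1 replicate 1, 18 without AAVS1 replicate 2, 4 without AAVS1 replicate 3, 17 without guide 395 replicate 1, 12 without guide 395 replicate 2 and 16 without guide 395 replicate 3. Among the lists, S phase was lost without AAVS1 replicate 1 (0.0806) or 2 (0.263), mitochondrially encoded transcripts without AAVS1 replicate 2 (0.0891) or guide 395 replicate 3 (0.0551), and cholesterol synthesis without AAVS1 replicate 1 (0.0702). The matrix list was lost without AAVS1 replicate 1 (0.0706), AAVS1 replicate 3 (0.108) or guide 395 replicate 2 (0.170). Apoptosis regulators were lost without AAVS1 replicate 1 (0.0850) or 2 (0.175) or guide 395 replicate 1 (0.146) or 3 (0.127), and MYC targets without AAVS1 replicate 1 (0.0806) or 2 (0.157) or guide 395 replicate 1 (0.0653), 2 (0.0985) or 3 (0.0551).

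Guide 395 in DDX3Xoe cells asks what remains of this response when codon-optimised DDX3X is supplied. Interferon-stimulated genes were higher as a list in the libraries labelled 395, with a median log2 fold change of 0.57 and 39 of 42 members above 0 (camera adjusted p 4.75e-07), and the call was lost with an estimated correlation (adjusted p = 0.992 with an estimated correlation). Among its members, MX2 had a log2 fold change of 1.52 and the RNA sensor gene IFIH1 one of 1.02, each with a limma adjusted p of 1. No gene passed in limma, with 315 (2.07% of those tested) at an unadjusted p under 0.05, and edgeR and DESeq2 also called 0. When no gene changes, a larger share than this reaches an unadjusted p under 0.05 on average, so the 315 are no sign of a remaining effect. Why the share was lower was not tested, and 0 called genes does not show that an effect is absent. Without both replicate 1 libraries the list kept its direction at a median of 0.45 (camera adjusted p 0.00324), and it passed without both replicate 2 (0.00193) or both replicate 3 libraries (7.17e-06). Its median was higher in the library labelled 395 in all 3 same-numbered pairs, by 0.48, 0.52 and 0.22. Without the library labelled AAVS1 replicate 1 alone its adjusted p was 0.841, and without the library labelled 395 replicate 2 alone it was 0.942. These omissions leave the numbers unequal between the guides, but the numbers were not taken to pair the libraries of this line. The list call thus depended on single libraries.

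In DDX3Yoe cells, where the same question was asked of the Y-linked paralogue, interferon-stimulated genes were higher with guide 395 by a median of 1.07, with 41 of 42 members above 0 (camera adjusted p 4e-33, adjusted p = 0.507 with an estimated correlation). BST2, which tethers virions, had a log2 fold change of 2.21, IFI27 one of 2.07 and TAP1 one of 1.04, each with a limma adjusted p of 1. The G2/M list was lower by a median of -0.45 (3.32e-07, adjusted p = 0.846 with an estimated correlation) and ribosomal protein genes by -0.19 (0.000778, adjusted p = 0.859 with an estimated correlation). Oxidative phosphorylation genes were lower by a median of -0.11 (0.00626, adjusted p = 0.846 with an estimated correlation) and matrix genes by -0.17 (0.0184, adjusted p = 0.846 with an estimated correlation), the latter with ACTA2 at -0.89 and an adjusted p of 1. Limma called 0 genes, with 153 (1.005% of those tested) at an unadjusted p under 0.05, and edgeR and DESeq2 called 0. This share too is below the one reached on average when no gene changes, and 0 called genes does not show that an effect is absent. The interferon list passed whichever library was left out, but its median differed by 0.53, 2.61 and 0.14 in the same-numbered pairs, and without both replicate 2 libraries its adjusted p was 0.0257. The G2/M median was lower with guide 395 in all 3 same-numbered pairs, by -0.20, -0.080 and -0.38, and the list passed without both libraries of replicate 1 (8.15e-06), 2 (1e-07) or 3 (0.000248). With 1 library left out, which leaves the numbers unequal between the guides, G2/M was lost without AAVS1 replicate 1 (0.881) and pointed up without guide 395 replicate 3 (0.340). Ribosomal proteins were lost without AAVS1 replicate 2 (0.199) or guide 395 replicate 2 (0.594), oxidative phosphorylation without AAVS1 replicate 1 (0.211), and matrix genes without AAVS1 replicate 1 (0.211) or guide 395 replicate 2 (0.375). The numbers were not taken to pair the libraries of this line either, so these list calls depended on single libraries. Without both replicate 2 libraries ribosomal proteins turned (0.746), and oxidative phosphorylation and matrix genes were lost without both libraries of replicate 1 (0.166 and 0.0580) or of replicate 2 (0.0651 and 0.157).

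The 271 genes called in parental cells moved less in both overexpressing lines. The slope through the origin of their guide effects on the parental ones was 0.0907 in DDX3Xoe cells (SE 0.0989 between libraries) and 0.236 in DDX3Yoe cells (SE 0.0805), where 1 would be an effect of equal size. An exact two-sided permutation test of the 6 libraries of a line gave p = 0.5 for DDX3Xoe and p = 0.1 for DDX3Yoe, the smallest that 3 against 3 libraries can give. Across genes, which are not independent replicates, 180 of the 271 (66.4%) had the parental sign in DDX3Xoe cells and 240 (88.6%) in DDX3Yoe cells. The DDX3Xoe slope was 0.00153 without the library labelled 395 replicate 2, 0.170 without the library labelled 395 replicate 1 and 0.159 without both replicate 1 libraries. It was 0.0563 without the library labelled AAVS1 replicate 2, and 0.0495, 0.0458 and 0.0415 without parental AAVS1 replicate 1, AAVS1 replicate 2 and guide 395 replicate 3. Genes chosen for passing in parental cells have parental effects that are too large on average, and with genes chosen on parental replicates 1 and 2 and the slope taken on replicate 3 the values were 0.0703 and 0.332. No group carried an empty vector, so an effect of the transgenes cannot be told apart from other differences between the lines. Differences near the AAVS1 site, given below, were also smaller in the overexpressing lines than in parental cells.

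**Figure D3:**
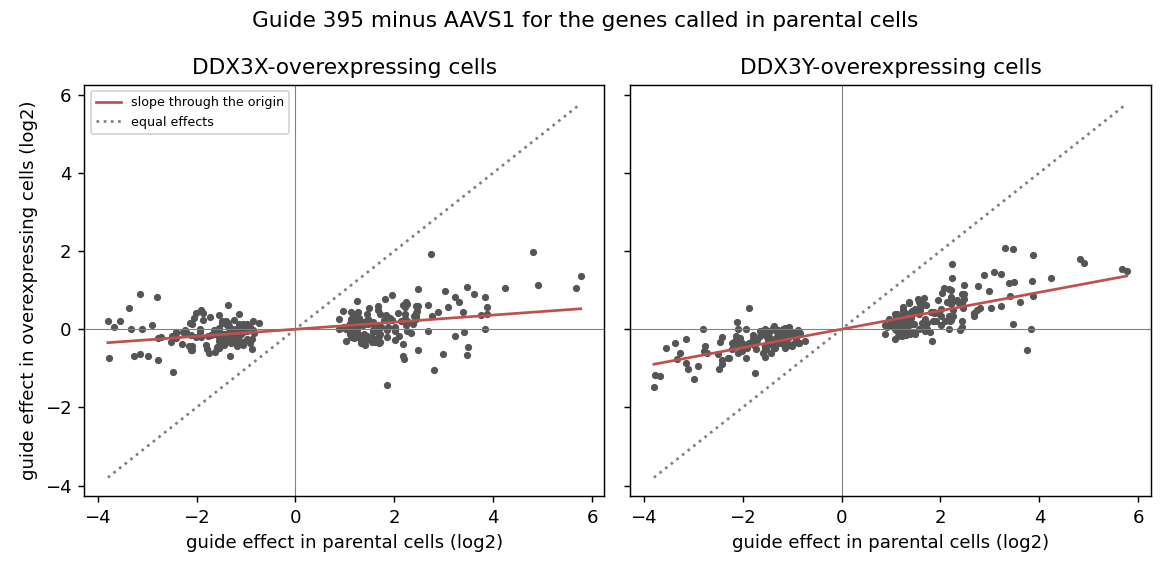
Guide effect (log2, 395 minus AAVS1) of the 271 genes called in parental cells, in parental cells (horizontal axis) and in DDX3Xoe (left) or DDX3Yoe cells (right, vertical axes). Each point is a gene, the red line is the slope through the origin, 0.0907 on the left and 0.236 on the right, and the dotted line marks equal effects.

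Whether the guide effect itself differed between cells was tested as a difference of effects. DDX3Xoe minus parental passed for 7 genes in limma, 3 higher and 4 lower. ACTA2 differed by 2.36 (SE 0.38, limma adjusted p 0.0384), since it fell in parental cells and had 740.8 ± 171 and 719.8 ± 229 normalised reads (SD, n = 3) in the libraries labelled DDX3Xoe with AAVS1 and 395. TMOD1 differed by 2.15 (adjusted p 0.0496) and PTRHD1 by 2.04 (0.0384), while ZDHHC8BP differed by -3.95, TOB2, an anti-proliferative gene, by -2.27 and CBARP, a calcium channel regulator, by -2.04 (each 0.0384). Interferon-stimulated genes differed as a list by a median of -1.19 (camera adjusted p 2.28e-08, adjusted p = 0.594 with an estimated correlation) and G2/M genes by 1.00 (2.27e-07, adjusted p = 0.594 with an estimated correlation), among 9 lists past the test. The gene count was 0 without both replicate 1 libraries labelled DDX3Xoe. It was 4 without parental AAVS1 replicate 1 or the library labelled DDX3Xoe with 395 replicate 2, 1 without the library labelled DDX3Xoe with AAVS1 replicate 3, and 0 without any other of the 12 libraries. It was 16 with the replicate number as a block, 6 with edgeR and 86 with DESeq2. Fits on these 4 groups alone called 1 gene.

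DDX3Yoe minus parental passed for 0 genes in limma, with 737 (4.84% of those tested) at an unadjusted p under 0.05. It passed for 0 in edgeR and 10 in DESeq2, which made 12 false calls for this comparison on simulated data. Of 7 lists past the test, NF-kB and inflammatory genes differed by a median of -1.06 (camera adjusted p 3.63e-05, adjusted p = 0.316 with an estimated correlation), where PTGS2 differed by -2.13 with a limma adjusted p of 0.581. Ribosomal protein genes differed by 0.50 (1.80e-08, adjusted p = 0.808 with an estimated correlation) and interferon-stimulated genes by -0.62 (0.000335, adjusted p = 0.808 with an estimated correlation), the latter lost without DDX3Yoe AAVS1 replicate 1 (0.137). DDX3Yoe minus DDX3Xoe, the direct test between the overexpressing lines, passed for 0 genes in limma, edgeR and DESeq2. In limma 227 (1.49%) had an unadjusted p under 0.05, a share below the one reached on average when no gene changes. Interferon-stimulated genes were higher by a median of 0.62 (camera adjusted p 0.00159, adjusted p = 0.977 with an estimated correlation) and G2/M genes lower by -0.45 (0.000428, adjusted p = 0.977 with an estimated correlation). Without both replicate 1 libraries labelled DDX3Xoe the interferon list passed (0.000136) and the G2/M list did not (0.129). The interferon call ended without DDX3Xoe AAVS1 replicate 2 (0.817) or 3 (0.354), DDX3Xoe 395 replicate 1 (0.868) or 3 (0.0583), or DDX3Yoe 395 replicate 2 (0.229), and turned without DDX3Yoe AAVS1 replicate 2 (0.867). The G2/M call ended without DDX3Xoe AAVS1 replicate 3 (0.354), DDX3Xoe 395 replicate 1 (0.868) or DDX3Yoe AAVS1 replicate 1 (0.722), and turned without DDX3Yoe 395 replicate 3 (0.878).

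Under the control guide, 5 lists were lower in DDX3Xoe and 4 in DDX3Yoe than in parental cells. Oxidative phosphorylation genes were lower by a median of -0.29 in DDX3Xoe (camera adjusted p 4.70e-06, adjusted p = 0.981 with an estimated correlation) and -0.32 in DDX3Yoe (0.000256, adjusted p = 0.953 with an estimated correlation). Both results rest on the same parental libraries, and both were lost without parental AAVS1 replicate 2 (0.180 and 0.328), and in DDX3Xoe also without the library labelled AAVS1 replicate 2 (0.321). Interferon-stimulated genes were lower by -0.37 in DDX3Xoe (0.0155, adjusted p = 0.981 with an estimated correlation) and -0.41 in DDX3Yoe (0.0166, adjusted p = 0.953 with an estimated correlation). These turned in direction without parental AAVS1 replicate 3 (0.671 and 0.907), the DDX3Xoe value also without the library labelled AAVS1 replicate 1 (0.117). Without DDX3Yoe AAVS1 replicate 2 the DDX3Yoe value turned and passed as higher (0.0495). Without both replicate 1 libraries labelled DDX3Xoe the DDX3Xoe value turned as well (0.107). Proteasome genes were lower by -0.18 in DDX3Xoe (0.00455, adjusted p = 0.693 with an estimated correlation) and -0.20 in DDX3Yoe (0.0320, adjusted p = 0.953 with an estimated correlation). Both were lost without parental AAVS1 replicate 2 (0.226 and 0.376), and the DDX3Yoe value without DDX3Yoe AAVS1 replicate 2 (0.0789) or 3 (0.0860). In DDX3Xoe, mitochondrially encoded transcripts were lower by -0.25 (0.0297, adjusted p = 0.981 with an estimated correlation), lost without parental AAVS1 replicate 1 (0.0601) or 2 (0.981) or the library labelled AAVS1 replicate 1 (0.0790) or 3 (0.237). Matrix genes were lower there by -0.21 (0.0312, adjusted p = 0.981 with an estimated correlation), lost without parental AAVS1 replicate 1 (0.358) or 3 (0.451) or the library labelled AAVS1 replicate 1 (0.133) or 2 (0.197). Both were lost without both replicate 1 libraries labelled DDX3Xoe (0.0563 and 0.132). That fit also passed further lists as lower in DDX3Xoe. These were ribosomal proteins at -0.28 (camera adjusted p 0.000562), cholesterol synthesis at -0.40 (0.00239), S phase at -0.46 (0.00314) and TGF-beta responsive genes at -0.43 (0.019). Oxidative phosphorylation genes stood at -0.50 in it (camera adjusted p 6.54e-09). In DDX3Yoe, ribosomal protein genes were lower by -0.15 (0.0360, adjusted p = 0.953 with an estimated correlation), lost without DDX3Yoe AAVS1 replicate 1 (0.173) or 3 (0.157) and turned without parental AAVS1 replicate 2 (0.924). No gene passed in limma, edgeR or DESeq2 for either line or between the lines. At an unadjusted p under 0.05 in limma there were 150 genes (0.985%) for DDX3Xoe, 402 (2.64%) for DDX3Yoe and 136 (0.893%) between them. Each share is below the one reached on average when no gene changes. Between the lines no list passed, and 5 did without both replicate 1 libraries labelled DDX3Xoe.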

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

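Of the tests in this part, the fits without both replicate 1 libraries labelled DDX3Xoe, the list tests with 1 library left out, the test of weaker editing, the chromosome 19 values and the PPP1R12C values were chosen only after the result was seen.

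The guide effect differed between DDX3Xoe and parental cells by a test of the difference for 7 genes: ACTA2 (2.36), TMOD1 (2.15), PTRHD1 (2.04), ZDHHC8BP (-3.95), TOB2 (-2.27), CBARP (-2.04) and KCNMB3 (-4.12, log2 scale). KCNMB3, a potassium channel subunit below the expression level that the naming rule asks for, was named after its values were seen. With limma, 5 of 100 splits of each guide's libraries between these cell lines, the real one included, called at least 7 genes. The highest other split called 1779. Chance was not excluded, and these splits cannot decide it. A split that keeps the guide 395 libraries of these cell lines apart still holds the difference between those libraries. The split with 1779 is of this kind: it sets all 3 DDX3Xoe libraries with guide 395 beside 2 of the 3 parental libraries with AAVS1. What drives its count was not tested.

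Gene lists differed between DDX3Xoe and parental cells by medians of -1.19 for interferon-stimulated genes, -1.02 for NF-kB and inflammatory genes, 0.49 for S phase, 1.00 for G2/M, 0.56 for ribosomal proteins, 0.26 for translation factors, 0.36 for oxidative phosphorylation, 0.37 for cholesterol synthesis and 0.39 for the proteasome. Between DDX3Yoe and parental cells the medians were -0.62 for interferon-stimulated genes, -1.06 for NF-kB and inflammatory genes, 0.41 for G2/M, 0.50 for ribosomal proteins, 0.24 for oxidative phosphorylation, 0.37 for mitochondrially encoded transcripts and 0.33 for the proteasome. Between DDX3Yoe and DDX3Xoe they were 0.62 for interferon-stimulated genes and -0.45 for G2/M. Each passed camera and none passed with an estimated correlation, where the adjusted p values lay between 0.316 and 0.977. Several camera calls ended with 1 library left out. For DDX3Xoe minus parental, S phase ended without parental AAVS1 replicate 1 (0.173) or 2 (0.428), parental 395 replicate 1 (0.0520) or 3 (0.0692), DDX3Xoe AAVS1 replicate 3 (0.829), or DDX3Xoe 395 replicate 1 (0.532) or 2 (0.236). Cholesterol synthesis ended without parental AAVS1 replicate 1 (0.170) or 2 (0.128), parental 395 replicate 2 (0.112), DDX3Xoe AAVS1 replicate 3 (0.482) or DDX3Xoe 395 replicate 1 (0.177), and translation factors (0.160) and oxidative phosphorylation (0.0716) without DDX3Xoe AAVS1 replicate 2. For DDX3Yoe minus parental, G2/M ended without parental AAVS1 replicate 1 (0.117), parental 395 replicate 1 (0.0804), or DDX3Yoe 395 replicate 1 (0.920) or 2 (0.103), and turned without DDX3Yoe AAVS1 replicate 3 (0.972). Mitochondrially encoded transcripts ended without parental AAVS1 replicate 2 (0.493), parental 395 replicate 3 (0.233), DDX3Yoe AAVS1 replicate 3 (0.181) or DDX3Yoe 395 replicate 1 (0.394), and with median-centring (0.0634). Oxidative phosphorylation ended without parental AAVS1 replicate 2 (0.106) and interferon-stimulated genes without DDX3Yoe AAVS1 replicate 1 (0.137). For DDX3Yoe minus DDX3Xoe the libraries are named in the report.

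Other splits of the samples were counted for the remaining comparisons too. In parental cells 1 of the 10 splits of 6 libraries, the real one, called 271 genes and the highest other called 0. Like the real one, 3 of the others part all 3 numbered pairs, and the other 6 part 1 pair. With 10 splits the share cannot fall under 0.05. The same limit holds for the guide effect in DDX3Xoe and in DDX3Yoe cells, where the real split called 0 and the highest other 0, and for the comparisons under the control guide, where the real split called 0 and the highest other 1 for DDX3Xoe and 0 for DDX3Yoe and between the lines. For DDX3Yoe minus parental the real split called 0 and the highest other of 100 called 41, and for DDX3Yoe minus DDX3Xoe 0 and 1. Any split reaches a real count of 0, all 10 or all 100 here, so for these counts the splits say nothing about chance.

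DDX3X reads ran against the guide labels in the replicate 1 libraries labelled DDX3Xoe. Counting noise is argued against: the library labelled 395 had 2.13 times the DDX3X reads per total of the one labelled AAVS1, with an exact 95% interval of 1.94 to 2.34. An exchange of these 2 labels predicts that genes beyond DDX3X towards the end of the short arm of chromosome X, lower with guide 395 elsewhere, are higher in the library labelled 395, and their median difference was 0.211 (0.0601 to 0.362 as 2 standard errors over genes), against -0.185 and -0.150 in replicates 2 and 3. PPP1R12C, the gene that holds the AAVS1 site, differed by -0.92 in this pair and by 0.70 and 0.25 in the others. Weaker editing in this pair predicts differences near 0. Genes beyond PPP1R12C on chromosome 19 had a median of -0.372 (-0.531 to -0.212 as 2 standard errors over genes), against 0.0025 and 0.29 in replicates 2 and 3. Intervals over neighbouring genes of 1 pair of libraries hold no spread between libraries, so these values do not decide between the explanations. The interferon median ran with the labels, at 9.29 in the library labelled 395 and 8.81 in the one labelled AAVS1. The labels may have been exchanged, which stays open, and no biological explanation was tested.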

How the results depend on the processing

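The block within each cell line, library quality weights, the fits without both DDX3Xoe replicate 1 libraries and the gene lists with 1 library, or both libraries of a number, left out were chosen after seeing the data. The cause of a change was not tested unless stated. With no single library left out, 552 results for named genes under other settings kept their direction and side of the threshold, 67 fell short of it and 2 turned. These results, here and with 1 library left out, include DDX3X in the differences of guide effects and between cell lines. It was not called there, so it had no call to lose. For single lists these were 142, 103 and 2. Answers to a comparison were counts of genes or lists, slopes, and the DDX3X guide effect. Of these 224 were kept, 41 moved and 2 newly passed, both for DDX3X in parental cells. For a count, kept means within 1.5 times, or still at 0. For a slope it means a change under 1 SD between libraries, and for DDX3X the same direction and side of the threshold. With 1 library left out, 144 results for named genes kept both, 143 fell short and 1 turned, and for single lists 301, 74 and 9. By the same rules 136 answers to a comparison were kept and 50 moved. For DDX3Xoe minus parental 12 fits each left out 1 library. The call of ZDHHC8BP was kept in 3 of them, those of ACTA2 and PTRHD1 in 2 each, and those of TMOD1, TOB2 and CBARP in 0.

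The parental count of 271 (149 higher, 122 lower) became 159 without a filter (106 and 53), 83 in the fit on the compared groups alone (66 and 17), 927 with DESeq2, 677 with the replicate block, 602 with the block and median-centring (249 and 353) and 737 with a block within each cell line. With 1 library left out, which leaves fewer samples, it was 60 to 366. For DDX3Xoe minus parental the count of 7 became 4 with median-centring, 4 without the intensity trend, 1 with the compared groups alone, 16 with the block, 11 with the block and centring, 86 with DESeq2, 57 with quality weights, 0 without both DDX3Xoe replicate 1 libraries and 0 to 4 with 1 library left out. Without a filter, guide 395 in DDX3Yoe called 1, DDX3Yoe minus parental 3, DDX3Yoe against parental under AAVS1 2 and DDX3Yoe against DDX3Xoe under AAVS1 3. DDX3Yoe minus parental called 1 without the trend and 10 with DESeq2, and quality weights, whose fit stopped before converging, called 24 between the lines under AAVS1.

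Of the named parental genes, the replicate block kept the call of 27 and added 11, each given in the report, and it ended the call of MYC targets. It called 0 genes in DDX3Xoe and in DDX3Yoe cells. Same-numbered correlations were 0.231, -0.0279 and 0.3 in DDX3Xoe cells and 0.0745, 0.114 and 0.238 in DDX3Yoe cells. These were not all above 0.1, so the numbers were not taken to pair those libraries, though they may share some structure. Only DDX3Xoe AAVS1 replicate 2 correlated better with another number (0.179) than with its own. Some list levels follow the number all the same: the ATF4 list stood at 10.62 to 10.68 in the replicate 3 libraries of these lines and at 9.45 or less in the others, while the parental replicate 3 libraries stood apart, at 10.52 with AAVS1 and 9.54 with guide 395. Of 45 same-numbered pairs over all groups, 29 correlated above 0.1.

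DDX3X in parental cells passed with DESeq2 (-1.05) and without both DDX3Xoe replicate 1 libraries (-1.03), and ranged from -1.08 to -0.99 with 1 library left out. Its difference DDX3Xoe minus parental, 0.70, became -0.00705 without both, and DDX3Yoe minus DDX3Xoe, -0.62, became 0.084. DDX3Yoe minus parental ranged from -0.036 to 0.18. DDX3Y had no reads to test, so its alternatives gave no value.

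Lists past the test numbered 0 in every comparison with an estimated correlation, and with fry 1 in parental cells and 0 elsewhere. With 1 library left out they were 8 to 14 in parental, 0 to 6 in DDX3Xoe and 2 to 12 in DDX3Yoe cells, 6 to 12 for DDX3Yoe minus parental, 0 to 7 for DDX3Yoe minus DDX3Xoe, and under AAVS1 3 to 8 for DDX3Xoe, 4 to 7 for DDX3Yoe and 0 to 5 between them. In DDX3Yoe cells they were 3 without both replicate 1 or both replicate 2 libraries, where ribosomal proteins turned without the latter (0.746). Without both DDX3Xoe replicate 1 libraries they were 1 for DDX3Yoe minus DDX3Xoe and 5 between the lines under AAVS1. Lists that turned with 1 library left out had adjusted p ranges of 1.04e-23 to 0.881 (G2/M, DDX3Yoe), 1.33e-10 to 0.972 (G2/M, DDX3Yoe minus parental), 7.65e-14 to 0.878 (G2/M, DDX3Yoe minus DDX3Xoe) and 3.36e-12 to 0.868 (interferon, same). Under AAVS1 they were 1.72e-10 to 0.671 (interferon, DDX3Xoe; 0.107 and turned without both DDX3Xoe replicate 1 libraries), 1.48e-09 to 0.907 (interferon, DDX3Yoe) and 0.000425 to 0.924 (ribosomal proteins, DDX3Yoe). The slopes moved by less than 1 SD between libraries under every alternative run for them. For DDX3Xoe that SD was 0.121, above the slope of 0.0907, so a slope of 0 would also count as unmoved. With 1 library left out the slope was 0.00153 to 0.170 in DDX3Xoe and 0.168 to 0.286 in DDX3Yoe cells. Count models, no filter, no trend, robust moderation, the compared groups alone, quality weights, the block with centring and the block within each line were not run for slopes. Depth limits DDX3Xoe with guide 395 replicate 2 most, at 5.67 M reads.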

Other observations

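In this part the stretches on chromosome 19 and the PPP1R12C values were chosen only after the result was seen.

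Several stress and identity groups did not pass the list test in parental cells. With guide 395, p53 targets had a median log2 fold change of -0.045 (camera adjusted p 0.897), ATF4 and integrated stress response genes -0.23 (0.356), chaperones of the endoplasmic reticulum 0.13 (0.639) and immediate early genes 0.25 (0.572, and 0.507 with the replicate number as a block), with 1 immediate early gene called higher. The median level of the immediate early list was higher with guide 395 in all 3 same-numbered parental pairs, by 0.52, 0.57 and 0.49. Hypoxia and glycolysis genes stood at -0.29 (0.12) and Wnt targets at 0.58 (0.343). Of cell type markers that a culture could hold, astrocyte markers had a median of -0.42 (0.18), neuron markers -0.16 (0.346), epithelial markers -0.22 (0.718) and neural stem cell markers 0.10, although the test pointed down (0.944), with 1 member called lower. Oligodendrocyte and endothelial markers had 4 tested members each and leukocyte markers 1, too few to test. Other DEAD-box helicases had a median of 0.12, with the test pointing down (0.944). For some lists the median level in same-numbered parental pairs ran against the median fold change. It was higher with guide 395 for epithelial markers (0.25, 0.0034 and 0.12). It was lower for neural stem cell markers (-0.085, -0.039 and -0.53) and DEAD-box helicases (-0.080, -0.17 and -0.15).

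Genes beyond DDX3X on the short arm of chromosome X were lower with guide 395. Over 96 tested genes the median was -0.37 in parental cells (69 below 0) and -0.20 in DDX3Yoe cells (78 below 0), and -0.034 in DDX3Xoe cells by label, or -0.16 (61 below 0) in their replicates 2 and 3, without the pair whose DDX3X reads run against the labels. The other 386 genes of chromosome X had medians of -0.13, -0.079 and -9.30e-05. An equal fall over the whole chromosome is argued against, since the rest lay 0.235 above the distal genes in parental cells (0.0534 to 0.416 as 2 standard errors over genes). In the same-numbered parental pairs the distal medians were -0.354, -0.246 and -0.269, and those of the rest -0.135, -0.144 and -0.132. The rest thus fell too (236 of 386 genes below 0), and a smaller change of the whole chromosome stays open. Of 12560 stretches of as many genes on other chromosomes, 0% had a median as low, the lowest being -0.225, which argues against a chance stretch of neighbours. These stretches overlap and come from the same libraries, so they do not test chance between libraries. A candidate explanation is loss of the chromosome end beyond a Cas9 break in some cells, which expression alone does not show.

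The AAVS1 site gave the mirror image. On chromosome 19, 110 tested genes beyond PPP1R12C (ENSG00000125503, 55090913 to 55117559 on the minus strand of GRCh38) were higher with guide 395, and so lower with AAVS1, by a median of 0.50 in parental and 0.30 in DDX3Yoe cells, and stood at -0.074 in DDX3Xoe cells by label, or 0.098 in their replicates 2 and 3. None of 11654 stretches on other chromosomes (0%) had a median as high in parental cells, the highest being 0.294. These stretches overlap as well, and the rest of chromosome 19 was not among them. Zinc finger genes, which crowd this region, were higher elsewhere too, with a median of 0.30 over 455 genes against 0.62 over 63 distal ones, and the difference of 0.316 (0.12 to 0.512 as 2 standard errors over genes) argues against them as the whole cause. PPP1R12C itself differed by 0.90 in parental and 0.69 in DDX3Yoe cells. Loss beyond the control guide's break may add to the 395 minus AAVS1 differences of these genes.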
